A study of Mus musculus with 8 samples.

How the data were processed

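The labels gave 8 samples of mouse MLL-AF9 leukemic cells, 1 Affymetrix array each, in 4 groups of 2 by hairpin (shLUC or shSirt1), agent (DMSO or 3 µM EPZ4777) and time in drug (6 days for shLUC, 21 days for shSirt1). Cells grew in medium with 15% serum, 20 ng/ml SCF, 10 ng/ml IL-3 and 10 ng/ml IL-6. The deposited values are intensity values made with RMA, per the submitters' processing notes, which give no version. RMA corrects the background, normalizes between arrays and summarises probes per probe set, and it shrinks low signals toward a common floor, so small values understate a change. The software version, the chip definition and whether the 8 arrays were processed together are not given in the sources used here. That the intensity values the authors deposited are linear was read from the values, which reach 24500.

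The log2 of each deposited intensity was taken with no pseudocount and no further normalization. Of 45101 probe sets 64 were controls and were left out. A table pairing probe sets with the platform's gene annotation gave 34945 of them 1 gene symbol and 932 several, and 9160 were not listed there and so are unnamed here. The update of symbols changed 0. Each gene was represented by its probe set with the highest mean over the 8 arrays among those with 1 symbol, which gave 18193 genes, 9010 of them with 2 or more probe sets. Dim genes were kept, no detection calls were used, and the lower quartile of log2 intensity lay between 3.75 and 3.84.

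Genes were tested with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8), with lmFit and eBayes on a model of the 4 group means over all 8 arrays, which left 4 residual degrees of freedom per gene. All groups shared 1 estimate of the spread because 2 arrays per group give too little alone, and an exact test of 2 against 2 arrays cannot go below p = 0.333. The 5 comparisons were EPZ4777 against DMSO in each hairpin arm, the difference of those effects, and cells labelled shSirt1 against shLUC in DMSO and in EPZ4777. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 with no fold limit. All p-values are two-sided.

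Named genes are the 10 with the largest rise and the 10 with the largest fall among those past the threshold that moved the same way in every code, or all if fewer. Symbols ending in Rik or starting with Gm and a number, LOC or an accession were counted but not named. Passing members of the gene lists with the largest differences are given as examples, and Sirt1, Suv39h1, Dot1l, Hoxa7, Hoxa9, Hoxa10 and Meis1 whatever their values. Suv39h1 was not analysed here. Groups, tests, gene lists, this rule and the alternatives were set before the data were examined, except where a choice is said to follow from the data.

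The 30 gene lists held 539 members, of which 486 had a gene row. They came from general knowledge of hematopoiesis, metabolism and signalling, and some genes stand on more than 1 list. Lists were tested with limma's camera with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and with an estimated correlation. Fry was run too, and its directional p tests whether a list's genes move one way on balance, its mixed p whether they change in either direction, and neither compares a list with other genes.

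The codes A4, D11, A1 and A5 join a DMSO and an EPZ4777 array in the titles, and what they stand for is not given in the sources used here. Over genes, the deviations of a code from its group mean correlated between DMSO and EPZ4777 at 0.293 for shLUC and 0.378 for shSirt1. With 2 codes per hairpin each is the mirror of the other, so these are 2 values and not 4. The same measure between unrelated codes was 0.040 in DMSO and 0.401 in EPZ4777. Each pair lay above 0.1, but not above the unrelated codes in EPZ4777, so the check gives the pairing no support of its own. The pairing rests on the codes shared in the titles, blocked counts had been seen during exploration, and fits with the code as a fixed block (2 residual degrees of freedom) or as a random block stand beside the results they move.

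The alternatives were the mean of a gene's probe sets, every probe set by itself, removal of dim genes, quantile normalization or median centring, a trended or robust variance, only the 4 arrays compared, the code as a block, other thresholds, and each array left out in turn. The gene test was tested on simulated data in 20 draws of the EPZ4777 comparison in shLUC cells over 18193 genes, 200 of them changed. The test recovered 2.3% of changes of 0.5 log2, 56.8% of 1, 93.5% of 2 and 97.3% of 3, with 5.16% of calls false. With the code as a block, in another 20 draws, it recovered 0.10%, 14.7%, 87.8% and 96.7%, with 5.46% false. The blocked draws kept the full spread of the unblocked ones and added a code effect of the same size. They therefore do not compare the sensitivity of the 2 fits in these data. In both kinds of draws the MYC and ribosome biogenesis list was lowered by 0.5 log2 in cells labelled shSirt1 in EPZ4777. Camera with the preset correlation and without the block found it in all 20 draws of each kind. The simulated genes varied independently, while that list's estimated correlation in the data was 0.713. The draws therefore do not test camera on correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probe sets without a single symbol were left out of the gene results.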

Results

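The study measured total RNA of mouse leukemic cells transformed by MLL-AF9, a fusion of the histone methyltransferase MLL with AF9, on 8 Affymetrix arrays. The cells carried a hairpin against luciferase (shLUC), a control with no mouse target, or a hairpin against Sirt1 (shSirt1), which encodes an NAD-dependent deacetylase. They were kept in DMSO or in 3 µM EPZ4777, an inhibitor of the histone H3 lysine methyltransferase DOT1L. The arrays fell into 4 groups of 2: shLUC in DMSO, shLUC after 6 days in EPZ4777, shSirt1 in DMSO, and shSirt1 after 21 days in EPZ4777. The labels give no time for the DMSO arrays, so a comparison with or between them may also hold a difference of time in culture. Each title also held a code, A4 or D11 for shLUC and A1 or A5 for shSirt1, and each code occurred once in DMSO and once in EPZ4777. The labels do not say that the 2 arrays of a group came from separate cultures, so every p-value measured only the spread between these samples, which may be technical. The median log2 intensity over all probe sets was between 5.22 and 5.28 on the 8 arrays, and the number of arrays limited the precision of each value.

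Sirt1 was measured by 1 probe set, which checked the hairpin labels. Its log2 intensity in DMSO was 9.46 (A4) and 9.58 (D11) in shLUC cells, 8.70 in A1 and 9.55 in A5. In EPZ4777 it was 9.44 (A4) and 9.83 (D11) in shLUC cells, 8.85 in A1 and 9.73 in A5. The A1 arrays therefore held 56.6% of the shLUC mean in DMSO and 57.8% in EPZ4777, and the A5 arrays 102% and 106%. Because Sirt1 was not lower on the A5 arrays, all cells with that label are called cells labelled shSirt1 throughout, and each direction between the hairpins is a direction between labels. The log2 difference, labelled shSirt1 minus shLUC, was -0.40 ± 0.36 (standard error, n = 2 arrays per group, limma adjusted p = 0.928) in DMSO and -0.35 ± 0.36 (limma adjusted p = 0.785) in EPZ4777. Without the A1 array it was 0.028 in DMSO and 0.090 in EPZ4777, and without the A5 array -0.82 and -0.79, so its sign turned with the A1 arrays. Dot1l did not pass the test in any comparison, with -0.060 ± 0.12 for EPZ4777 in shLUC cells and -0.10 ± 0.12 in cells labelled shSirt1. Suv39h1 was not analysed here.

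**Figure D1:**
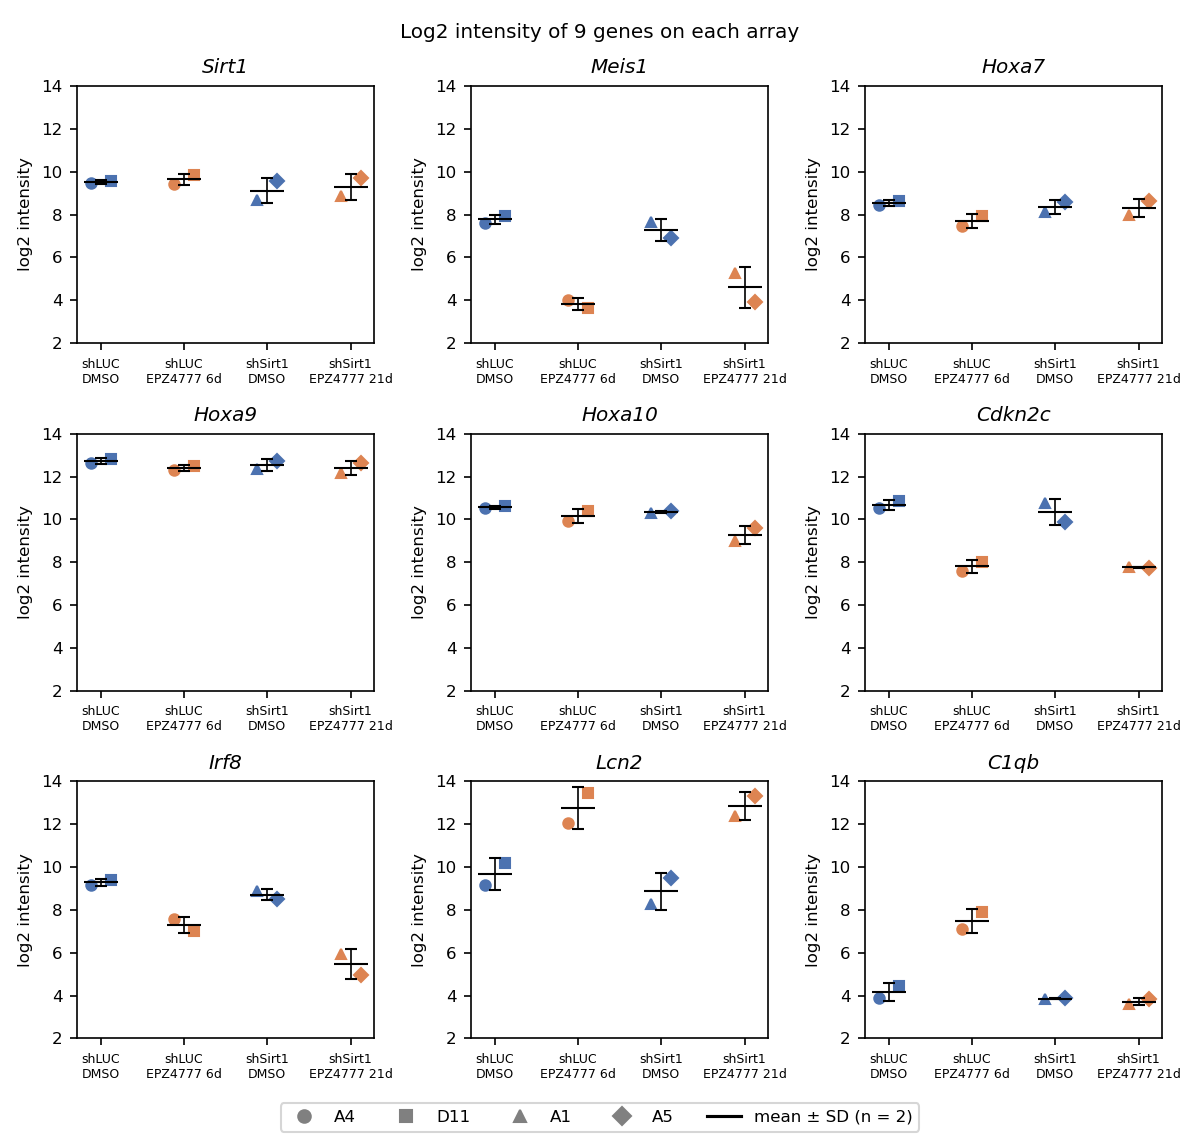
Log2 intensity (y axis) of 9 genes on each of the 8 arrays, with the groups on the x axis, 1 symbol shape per code and a black bar for the mean ± SD of the 2 arrays of a group. Sirt1 lay at 8.70 and 8.85 on the A1 arrays and at 9.44 or above on the others, and Meis1 fell by 3.96 on the log2 scale with EPZ4777 in shLUC cells.

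The comparison of EPZ4777 with DMSO in shLUC cells asked which transcripts changed when DOT1L was inhibited for 6 days. Meis1, a homeobox cofactor of HOX proteins and a target of MLL fusions, fell by 3.96 on the log2 scale (standard error 0.44, n = 2 arrays per group, limma adjusted p = 0.0244). Cd177, a neutrophil surface protein, and Lcn2, a neutrophil granule protein, rose (3.95 ± 0.72 and 3.07 ± 0.62, log2 difference ± standard error as in all brackets that follow). Mrc1, the macrophage mannose receptor, Mmp12, the macrophage elastase, and C1qb, a chain of complement C1q, also rose (4.19 ± 0.80, 3.63 ± 0.49 and 3.33 ± 0.28). Cdkn2c, an inhibitor of cyclin-dependent kinases, and Irf8, a transcription factor of monocytes and dendritic cells, fell (-2.87 ± 0.29 and -1.99 ± 0.33). The other largest rises were Nrep (3.65 ± 0.67), Pla2g7 (3.19 ± 0.54), Fstl1 (3.02 ± 0.45), Mogat2 (2.99 ± 0.32) and Maf (2.97 ± 0.61). The other largest falls were Glra3 (-3.21 ± 0.56), Cgnl1 (-2.20 ± 0.32), Ly86 (-2.15 ± 0.39), Arrdc3 (-2.11 ± 0.20), Amot (-2.08 ± 0.38), Bex6 (-1.84 ± 0.35) and Fgfbp3 (-1.84 ± 0.23). These 20 genes moved the same way in A4 and D11, with adjusted p from 0.0221 to 0.0477. Of the 5 probe sets of Cgnl1 4 had this sign, with 0 past the threshold the other way. Of 18193 genes, 724 passed (295 higher and 429 lower), of which 152 and 82 changed by 1 log2 or more, and 3945 had an unadjusted p under 0.05 where chance gives 910. A fit with the code as a block, called the blocked fit below, called 1316 (660 higher and 656 lower), 682 of them among the 724, and after quantile normalization of the arrays 601 passed (336 higher and 265 lower). The count depended on the arrays entered: with 1 array left out, its pair no longer entered the shared spread. Without either shLUC array in DMSO the calls were lost. That pair had the smallest spread between its arrays (SD 0.21, against 0.34 to 0.43 in the other groups). The calls in cells labelled shSirt1, given below, were then lost too. No shLUC array in DMSO enters that comparison, so that loss came through the shared spread. Most calls were also lost without D11 in EPZ4777, and fewer genes passed when either DMSO array labelled shSirt1 was left out.

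The list of MLL-AF9 targets lay lower in shLUC cells. Of 20 measured members 0 rose, 3 fell and 17 did not pass, and adjusted over the list alone 7 fell (0 higher and 5 lower in the blocked fit over all genes). The 3 were Meis1, Mef2c (-1.28 ± 0.23) and Cdk6 (-0.66 ± 0.13). Cdk6 missed the threshold in the blocked fit (adjusted p = 0.0515). The median was -0.40 and the camera adjusted p was 0.000701, against adjusted p = 0.368 with an estimated correlation. Fry, which tests whether a list moves one way on balance without comparing it with other genes, gave an adjusted p of 0.0334. None of the 9 measured HoxA genes passed over all genes, and 4 fell adjusted over the list alone (0 higher and 3 lower in the blocked fit over all genes). The median of the HoxA list was -0.41 and its camera adjusted p was 0.00633, against adjusted p = 0.497 with an estimated correlation. Hoxa7 measured -0.86 ± 0.26 (adjusted p = 0.114, or 0.0300 in the blocked fit, under which it fell), Hoxa9 -0.34 ± 0.20 (adjusted p = 0.392) and Hoxa10 -0.41 ± 0.23 (adjusted p = 0.362).

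Of the marker lists of blood cells 5 lay higher in shLUC cells by camera with the preset correlation, although most of their members did not pass, and the antigen presentation and dendritic, eosinophil, erythroid, T and NK cell and B cell lists were not called (smallest camera adjusted p 0.538). All 20 measured genes of neutrophil maturation had a positive difference, with a median of 1.80. Of these 3 rose, 0 fell and 17 did not pass, and 6 rose adjusted over the list alone (9 higher and 0 lower in the blocked fit over all genes). The 3 were Cd177, Lcn2 and Fcnb (2.31 ± 0.45). The camera adjusted p was 2.29e-08, against adjusted p = 0.526 with an estimated correlation. Of 24 monocyte and macrophage genes 5 rose, 1 fell and 18 did not pass, and adjusted over the list alone 7 rose and 2 fell (8 higher and 2 lower in the blocked fit over all genes). The list's median was 0.61 and its camera adjusted p was 0.00586, against adjusted p = 0.707 with an estimated correlation. The rises were in Mrc1, C1qb, Msr1, a scavenger receptor (1.86 ± 0.36), and C1qa and C1qc, the other chains of C1q (1.78 ± 0.25 and 1.68 ± 0.33), and the fall was in Irf8. Of 9 primary granule genes 1 rose, Gfi1, a transcriptional repressor needed for neutrophils (1.13 ± 0.12), 0 fell and 8 did not pass, and 3 rose adjusted over the list alone (3 higher and 0 lower in the blocked fit). Its camera adjusted p was 0.0408, against adjusted p = 0.497 with an estimated correlation. Of 11 megakaryocyte genes 1 rose, the platelet chemokine Pf4 (2.71 ± 0.19, adjusted p = 0.00979), 0 fell and 10 did not pass, with 1 rise adjusted over the list alone (2 higher and 0 lower in the blocked fit). Its camera adjusted p was 0.0189, against adjusted p = 0.497 with an estimated correlation. None of the 16 mast cell and basophil genes passed, 0 adjusted over the list alone, with a median of 0.20. Its camera adjusted p was 0.0374, against adjusted p = 0.497 with an estimated correlation.

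The MYC and ribosome biogenesis list lay lower in shLUC cells by the same test. Of its 24 members 10 fell, 0 rose and 14 did not pass, and adjusted over the list alone 22 fell and 1 rose. The falls included Odc1, the first enzyme of polyamine synthesis (-1.09 ± 0.16), Rrp12 (-0.90 ± 0.14), Nolc1 (-0.89 ± 0.18) and Srm, spermidine synthase (-0.89 ± 0.18). The list's median was -0.73 and its camera adjusted p was 4.24e-13, against adjusted p = 0.497 with an estimated correlation. Of 21 genes of the ATF4 and unfolded protein response 2 fell, the cystine transporter Slc7a11 (-1.36 ± 0.19) and Trib3 (-1.10 ± 0.19), 0 rose and 19 did not pass, and adjusted over the list alone 3 fell and 1 rose (1 higher and 4 lower in the blocked fit over all genes). Its camera adjusted p was 0.0189, against adjusted p = 0.751 with an estimated correlation. Of 20 genes of glycolysis and hypoxia 1 fell, the carbonic anhydrase Car9 (-0.71 ± 0.14), and 0 rose, with 1 fall adjusted over the list alone (0 higher and 2 lower in the blocked fit), and the camera adjusted p was 0.0189, against adjusted p = 0.751 with an estimated correlation. The median of that list was -0.032 in A4 and -0.42 in D11, so its lower value rested on D11. None of 27 genes of mitochondrial respiration passed, 0 adjusted over the list alone (0 higher and 1 lower in the blocked fit), with a median of -0.20, and the camera adjusted p was 0.00966, against adjusted p = 0.751 with an estimated correlation. Of 21 FOXO targets 4 rose, 0 fell and 17 did not pass: Il7r (1.69 ± 0.23), the insulin receptor Insr (0.94 ± 0.14), Cited2 (0.65 ± 0.12) and Foxo1 (0.63 ± 0.13). Of the 3 probe sets of Insr 2 had this sign, with 0 past the threshold the other way. Adjusted over the list alone 6 rose and 2 fell (5 higher and 1 lower in the blocked fit over all genes), and the camera adjusted p was 0.0189, against adjusted p = 0.526 with an estimated correlation. Of 24 interferon response genes 2 rose, Rtp4 (1.13 ± 0.18) and the RNA sensor Ddx58 (1.03 ± 0.20), 0 fell and 22 did not pass, and 5 rose adjusted over the list alone. Its camera adjusted p was 0.00925, against adjusted p = 0.497 with an estimated correlation. When only genes above the median level of all genes were tested, 3 of the 13 lists called in shLUC cells were still called: MLL-AF9 targets, neutrophil maturation, and MYC and ribosome biogenesis.

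The same comparison in cells labelled shSirt1 asked what changed after 21 days in EPZ4777. Olfm4, a neutrophil granule protein, rose (3.61 ± 0.49), and so did Smad1, a transducer of BMP signals (3.24 ± 0.37), Inhba, a subunit of activin (3.09 ± 0.41), and S100a6, a calcium-binding protein (2.92 ± 0.40). Irf8 fell (-3.25 ± 0.33), as did Ccr2, a chemokine receptor of monocytes (-2.95 ± 0.28), and Cdkn2c (-2.57 ± 0.29). The other largest rises were Cldn1 (3.47 ± 0.35), Penk (3.35 ± 0.41), Cd200r4 (3.15 ± 0.39), Pknox2 (3.01 ± 0.40), Plxnc1 (2.77 ± 0.25) and Stx3 (2.73 ± 0.18). The other largest falls were Glra3 (-4.48 ± 0.56), Cgnl1 (-2.90 ± 0.32), Ifi209 (-2.89 ± 0.36), Tifab (-2.29 ± 0.25), Muc13 (-2.22 ± 0.26), Arhgap12 (-1.96 ± 0.23) and Nt5c3b (-1.90 ± 0.27). These 20 genes moved the same way in A1 and A5, with adjusted p from 0.0127 to 0.0492 in limma. Meis1 measured -2.68 ± 0.44 (adjusted p = 0.0694, or 0.0146 in the blocked fit, under which it fell). Only 2 of the 3 probe sets of Meis1 and 3 of the 4 of Cldn1 had the sign given here, with 0 past the threshold the other way. Hoxa10 measured -1.05 ± 0.23 (adjusted p = 0.121), Hoxa7 -0.046 ± 0.26 (adjusted p = 0.950) and Hoxa9 -0.14 ± 0.20 (adjusted p = 0.770). In all 72 genes passed (39 higher and 33 lower), 37 and 27 of them by 1 log2 or more, and 2876 had an unadjusted p under 0.05. The blocked fit called 404 (239 higher and 165 lower), all 72 among them. Limma called 0 genes without the A4 or the D11 array of shLUC in DMSO (2248 at an unadjusted p under 0.05 for each) or without A1 in DMSO (2187), 1 without A5 in EPZ4777, 37 without A1 in EPZ4777, 121 when either shLUC array in EPZ4777 was left out, and 205 without A5 in DMSO.

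All 20 neutrophil maturation genes again had a positive difference in cells labelled shSirt1, with a median of 2.61. None passed over all genes (11 higher and 0 lower in the blocked fit), and 18 rose adjusted over the list alone, among them Cd177 (4.42 ± 0.72, adjusted p over all genes = 0.0690, or 0.0121 in the blocked fit) and Lcn2 (3.98 ± 0.62, adjusted p over all genes = 0.0655, or 0.00292 in the blocked fit). The camera adjusted p was 3.38e-14, against adjusted p = 0.794 with an estimated correlation. MLL-AF9 targets lay lower as a list, with a median of -0.39, although 0 of 20 passed over all genes (0 higher and 2 lower in the blocked fit) and 5 fell adjusted over the list alone. The camera adjusted p was 0.000302, against adjusted p = 0.330 with an estimated correlation, and fry gave an adjusted p of 0.00583. For the HoxA list 0 of 9 passed (0 higher and 2 lower in the blocked fit), 3 fell adjusted over the list alone, the median was -0.22, and the camera adjusted p was 0.00951, against adjusted p = 0.794 with an estimated correlation. All 24 MYC and ribosome biogenesis genes had a negative difference, none passed over all genes or adjusted over the list alone, and the median was -0.31. The camera adjusted p was 4.49e-06, against adjusted p = 0.794 with an estimated correlation. None of 27 mitochondrial respiration genes (median -0.25) and none of 20 glycolysis and hypoxia genes (median -0.29) passed over all genes, and adjusted over the list alone the counts were 0 and 1 (lower). The blocked fit called 0 of the former and 1 of the latter, lower, over all genes. Their camera adjusted p were 0.000183 and 0.000368, each with adjusted p = 0.794 with an estimated correlation. For the ATF4 and unfolded protein response 0 of 21 passed (0 higher and 1 lower in the blocked fit), 0 adjusted over the list alone, the median was -0.15, and the camera adjusted p was 0.0148, against adjusted p = 0.829 with an estimated correlation. The NF-kB and inflammation list lay higher (median 0.21) with 0 of 21 past over all genes (2 higher and 1 lower in the blocked fit), 3 rises and 1 fall adjusted over the list alone, and camera adjusted p = 0.0482; adjusted p = 0.794 with an estimated correlation. For the megakaryocyte list the median was 0.22 with 0 of 11 past (1 higher and 0 lower in the blocked fit), 0 adjusted over the list alone, and camera adjusted p = 0.0492; adjusted p = 0.794 with an estimated correlation. The stroma list lay lower (median -0.56) with 0 of 12 past (0 higher and 1 lower in the blocked fit), 0 adjusted over the list alone, and camera adjusted p = 0.0493; adjusted p = 0.794 with an estimated correlation. Within codes its median was -0.67 in A1 and -0.0040 in A5, so the call rested on A1. That list differed by array, in 2 members named after their values were seen. Col3a1, a fibrillar collagen chain, was at 6.92 on the A1 array in DMSO and at 3.13 or lower on the other 7, and Dcn, a matrix proteoglycan, at 7.27 against 4.79 or lower. Among the monocyte and macrophage genes 0 rose and 2 fell, Irf8 and Ccr2, of 24 (1 higher and 2 lower in the blocked fit), the same 2 fell adjusted over the list alone, and the list itself was not called (median -0.13, camera adjusted p = 0.679; adjusted p = 0.912 with an estimated correlation). H2-DMa, which loads peptide onto MHC class II, fell in both arms (-0.90 ± 0.19 in shLUC and -1.62 ± 0.19 in cells labelled shSirt1).

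Whether EPZ4777 moved the same genes in both arms was described over all 18193 genes. The 2 arms shared 28 genes that rose, where independent lists give 0.632, and 16 that fell, where they give 0.778, and 0 went opposite ways. Glra3, Cgnl1, Cdkn2c and Irf8 were among the largest falls in both. Of the 724 genes called in shLUC cells 668 (92.3%) had the same sign in cells labelled shSirt1, and of the 72 called there 69 (95.8%) had the same sign in shLUC cells. The effects correlated across genes with Pearson r 0.649 and Spearman rho 0.523, where genes are not independent replicates, and their SD over genes was 0.42 in shLUC and 0.43 in cells labelled shSirt1. The 2 comparisons share no array but 1 estimate of the spread. Within codes r was 0.741 between A4 and D11, 0.585 between A1 and A5, 0.366 between A4 and A1, and 0.719 between D11 and A5. The 300 genes that were higher by 1 log2 or more in A4 (median 1.32) had medians of 1.67 in D11, 0.80 in A1 and 1.18 in A5, and the 108 lower genes (median -1.17) had -1.37, -0.62 and -0.86. Picked in D11 instead, 626 higher genes (median 1.38) had medians of 0.84 in A4, 0.73 in A1 and 1.11 in A5, and 344 lower genes (median -1.20) had -0.71, -0.45 and -0.84. In the blocked fit 248 genes were shared in direction and 4 went opposite ways. The count of 44 shared genes fell to 0 when 1 array was left out, be it either shLUC array in DMSO, A1 in DMSO or A5 in EPZ4777, to 1 without D11 in EPZ4777 and to 18 without A1 in EPZ4777, and was 90 without A4 in EPZ4777.

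**Figure D2:**
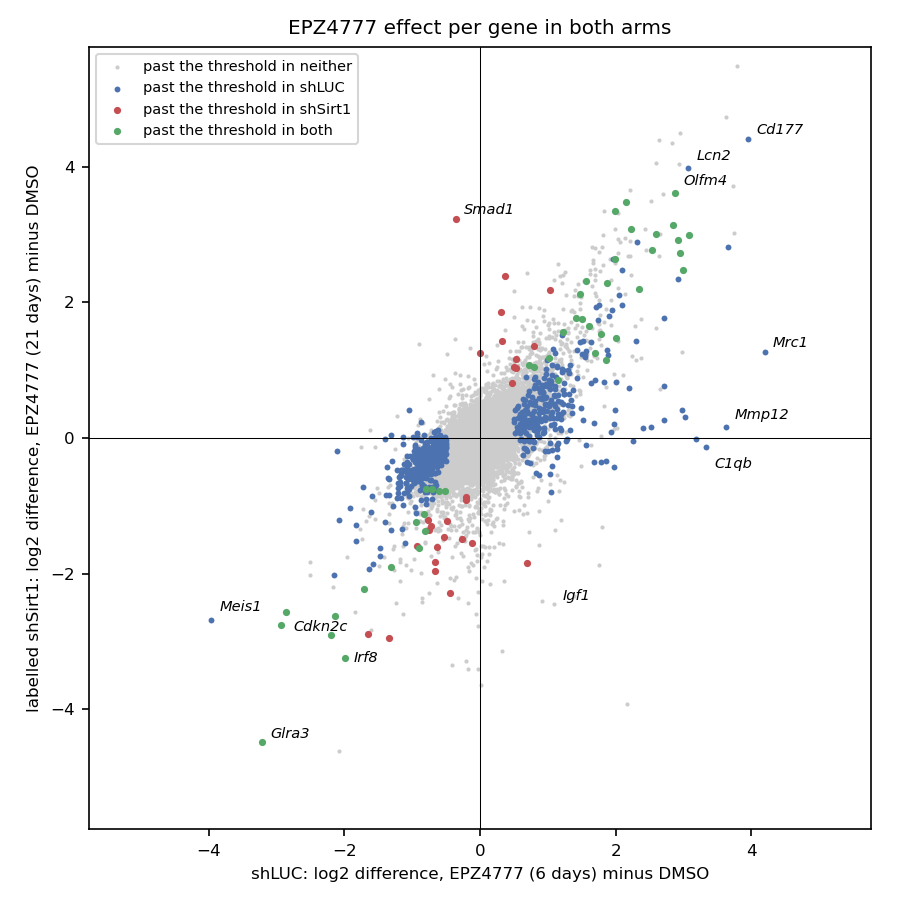
EPZ4777 minus DMSO log2 difference of each of 18193 genes in shLUC cells after 6 days (x axis) and in cells labelled shSirt1 after 21 days (y axis), with 1 point per gene coloured by the arm in which it passed the test. Most called genes had the same sign in both arms, while Mmp12 measured 3.63 against 0.16 and C1qb 3.33 against -0.13.

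A test of the difference between the 2 arms' effects asked whether cells labelled shSirt1 responded otherwise to EPZ4777. Hairpin label and days in drug (6 against 21) changed together, so a difference belongs to both. The monocyte and macrophage list had the lower effect in cells labelled shSirt1, with a median difference of effects of -0.67 (camera adjusted p = 1.50e-05; adjusted p = 0.574 with an estimated correlation), and of -0.20 over the 17 members above the median level of all genes. The effect on C1qb was 3.33 in shLUC cells and -0.13 in cells labelled shSirt1, a difference of -3.47 ± 0.40 (adjusted p = 0.202). On the arrays labelled shSirt1 C1qb lay between 3.60 and 3.87, beside a lower quartile of all probe sets between 3.75 and 3.84. MYC and ribosome biogenesis genes had the less negative effect in cells labelled shSirt1, with a median difference of 0.39 (camera adjusted p = 2.00e-06; adjusted p = 0.611 with an estimated correlation). Within codes the MYC list's median was -0.56 in A4, -0.95 in D11, -0.17 in A1 and -0.49 in A5, so A4 and A5 lay close and D11 and A1 far apart. Neutrophil maturation genes had the higher effect in cells labelled shSirt1, with a median difference of 0.75 (camera adjusted p = 0.0329, or 0.887 with an estimated correlation). Within codes, though, the median in D11 (2.40) lay above that in A1 (2.29). Labelled shSirt1 against shLUC, the list's median level was -0.89 in DMSO (-1.41 in A1 and -0.21 in A5) and 0.035 in EPZ4777. The higher effect thus went with a lower level in DMSO, mostly on the A1 array. Limma called 0 of 18193 genes, with 1221 at an unadjusted p under 0.05 and a smallest adjusted p of 0.150. The blocked fit called 3, named here after their values were seen: C1qb (adjusted p = 0.0244), the collagenase Mmp13 (-3.63, adjusted p = 0.0247) and Smad1 (3.59, adjusted p = 0.0244). As a random block, the code gave 3 lower genes, C1qb, Ahnak and C3ar1, the last also named after its values were seen. The count was 89 without the A5 array in DMSO and 2 without A1 in EPZ4777.

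Lower effects in cells labelled shSirt1 were also called for antigen presentation and dendritic genes (median difference -0.28, camera adjusted p = 0.00828; adjusted p = 0.574 with an estimated correlation). In that list 0 of 14 genes passed over all genes or adjusted over the list alone. The FOXO targets (median -0.40; camera adjusted p = 0.00172; adjusted p = 0.574 with an estimated correlation) had 0 of 21 past over all genes, and 3 lower and 1 higher adjusted over the list alone. Within codes the FOXO median was 0.29 in A4, 0.37 in D11, -0.35 in A1 and 0.23 in A5, so the lower effect rested mainly on A1. The interferon response (median -0.29; camera adjusted p = 0.000359; adjusted p = 0.574 with an estimated correlation) had 0 of 24 past over all genes and 1 lower adjusted over the list alone. The stroma list (median -0.35; camera adjusted p = 0.0201; adjusted p = 0.574 with an estimated correlation) had 0 of 12 past and 0 adjusted over the list alone, with Col3a1 at 6.92 on A1 in DMSO and 3.13 or lower elsewhere, and within codes its median was negative beyond -0.062 in A1 alone. The DOT1L and MLL complex list (median -0.17; camera adjusted p = 0.0201; adjusted p = 0.574 with an estimated correlation) had 0 of 14 past over all genes and 1 lower adjusted over the list alone. In A4, D11, A1 and A5 the medians were 0.12, 0.015, -0.16 and -0.077 for antigen presentation, 0.17, 0.27, -0.050 and 0.040 for the interferon response, and 0.22, 0.10, -0.11 and -0.15 for the DOT1L and MLL complex. In the macrophage list 0 of 24 passed and 6 were lower adjusted over the list alone (0 higher and 1 lower in the blocked fit over all genes), in the MYC list 0 of 24 passed and 0 adjusted over the list alone, and in the neutrophil list 0 of 20 passed and 0 adjusted over the list alone. The blocked fit called 2 more lists, primary granule genes (lower, adjusted p = 0.0491, against 0.0511 without it) and p53 targets (higher, adjusted p = 0.0390, against 0.0644). With an estimated correlation, without the block, their adjusted p were 0.574 and 0.711. MLL-AF9 targets were not called, with a median difference of 0.11 (camera adjusted p = 0.720).

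**Figure D3:**
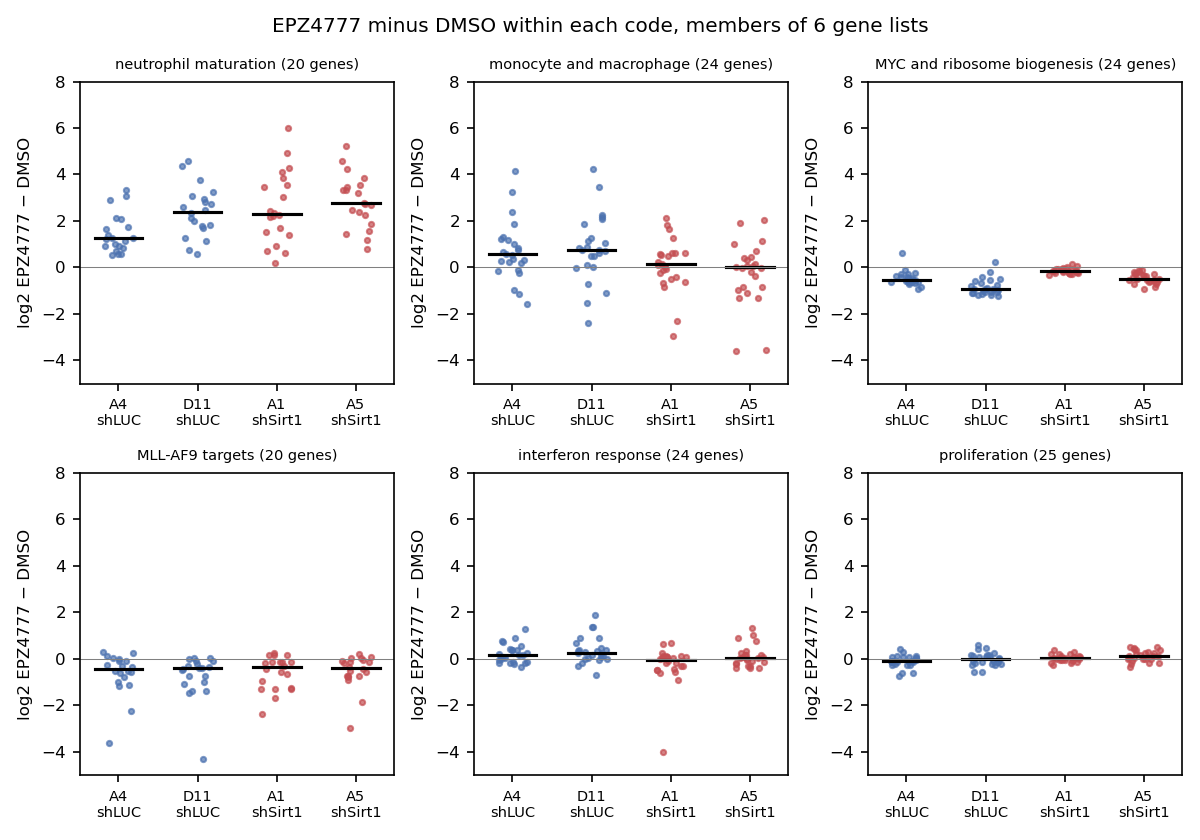
EPZ4777 minus DMSO log2 difference (y axis) of each member of 6 gene lists within each code (x axis), with 1 dot per gene and a bar at the list's median. The neutrophil maturation medians were 1.25 (A4), 2.40 (D11), 2.29 (A1) and 2.76 (A5), and the monocyte and macrophage medians 0.56, 0.75, 0.13 and 0.0020.

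In DMSO the comparison of cells labelled shSirt1 with shLUC cells asked what differed by hairpin label without drug. No time is given for these arrays, so the labels may also differ in time in culture. The monocyte and macrophage list was lower in cells labelled shSirt1, with a median of -1.10 and a negative difference in 22 of 24 genes. Its 3 lowest members, named after their values were seen, were Gpnmb (-2.14 ± 0.55, adjusted p = 0.882), the transcription factor Klf4 (-1.89 ± 0.33, adjusted p = 0.882) and Mpeg1, a macrophage perforin (-1.87 ± 0.59, adjusted p = 0.882). Against the shLUC mean, the list's median was -1.65 in A1 and -0.68 in A5. None of the 24 passed over all genes, 6 were lower adjusted over the list alone, and the camera adjusted p was 2.68e-12, against adjusted p = 0.651 with an estimated correlation. The neutrophil maturation list was lower too (median -0.89, camera adjusted p = 0.000208; adjusted p = 0.651 with an estimated correlation), at -1.41 in A1 and -0.21 in A5. The cholesterol synthesis list was lower (median -0.41, camera adjusted p = 2.80e-05; adjusted p = 0.651 with an estimated correlation), at -0.097 in A1 and -0.66 in A5, where Sirt1 was not lower. The NF-kB and inflammation list was lower (median -0.23, camera adjusted p = 0.000399; adjusted p = 0.651 with an estimated correlation), with 1 gene lower adjusted over the list alone. Higher were the DOT1L and MLL complex list (median 0.28, camera adjusted p = 2.80e-05; adjusted p = 0.651 with an estimated correlation), mitochondrial respiration (median 0.098, camera adjusted p = 0.00544; adjusted p = 0.651 with an estimated correlation) and FOXO targets (median 0.11, camera adjusted p = 0.0179; adjusted p = 0.651 with an estimated correlation). Against the shLUC mean, mitochondrial respiration was at 0.20 in A1 and -0.013 in A5, and FOXO targets at 0.29 and 0.0010, so both calls rested on A1, while the DOT1L and MLL complex was at 0.34 and 0.21. In these 7 lists 0 members passed over all genes, and except for the 6 and the 1 already given 0 passed adjusted over the list alone. Limma called 0 of 18193 genes, with 985 at an unadjusted p under 0.05 where chance gives 910 and a smallest adjusted p of 0.796. Without the A5 array in DMSO it called 155. The stroma list was not called (median 0.17, camera adjusted p = 0.132), with a median against the shLUC mean of 0.42 on A1, the array high in Col3a1, and -0.024 on A5.

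In EPZ4777 the comparison of cells labelled shSirt1 (21 days) with shLUC cells (6 days) is again one of hairpin label and time together. Of the monocyte and macrophage list, C1qb (-3.77 ± 0.28), the lysosomal protease Ctss (-3.26 ± 0.29) and Msr1 (-3.24 ± 0.36) were among the lower genes in cells labelled shSirt1. Mmp12, which is not on that list, was lower too (-3.84 ± 0.49). Igf1, insulin-like growth factor, was lower (-4.54 ± 0.45), and Smad1 was higher (4.12 ± 0.37). Perp, a p53 target (3.03 ± 0.31), and the transporter Abcg2 (2.34 ± 0.30) were higher as well. The other largest higher values were Bhlhb9 (2.21 ± 0.28), Arrdc3 (1.94 ± 0.20), Cxadr (1.48 ± 0.19), Osm (1.35 ± 0.18), Klf11 (1.08 ± 0.14), Agbl5 (1.07 ± 0.13) and Pkp2 (1.06 ± 0.12). Only 1 of the 3 probe sets of Agbl5 and 3 of the 4 of Pkp2 had this sign, with 0 past the threshold the other way. The other largest lower values were Wfdc17 (-4.55 ± 0.58), Csn2 (-3.61 ± 0.40), Klk1b11 (-3.45 ± 0.40), Ahnak (-3.20 ± 0.17) and Ccl7 (-3.16 ± 0.41). On these 20 genes both arrays of one group lay above both of the other, with adjusted p from 0.00292 to 0.0421. The shLUC EPZ4777 arrays also entered the drug comparison in which C1qb, Mmp12 and Msr1 rose. Igf1 was not called with EPZ4777 in either arm (1.09 ± 0.45, adjusted p = 0.223, and -2.45 ± 0.45, adjusted p = 0.0865), though in the blocked fit it fell in cells labelled shSirt1 (adjusted p = 0.0284). Of 18193 genes 56 passed (12 higher and 44 lower), and 2427 had an unadjusted p under 0.05. Limma called 0 without D11 of shLUC in EPZ4777 (1986 at an unadjusted p under 0.05), 2 without the A4 or the D11 array of shLUC in DMSO, 11 without A5 in EPZ4777 and 15 without A4 in EPZ4777.

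Of the 24 monocyte and macrophage genes 5 were lower in EPZ4777, 0 higher and 19 did not pass, and 15 were lower adjusted over the list alone, with a median of -2.03. The 5 were C1qb, Ctss, Msr1, Ccr2 (-2.70 ± 0.28) and C1qa (-2.07 ± 0.25). The camera adjusted p was 1.12e-18, against adjusted p = 0.342 with an estimated correlation. The median against the shLUC mean was -2.20 in A1 and -1.86 in A5. Antigen presentation and dendritic genes (0 of 14 past, 7 lower adjusted over the list alone, median -0.44; camera adjusted p = 4.21e-05; adjusted p = 0.451 with an estimated correlation) and the interferon response (0 of 24 past, 9 lower adjusted over the list alone, median -0.33; camera adjusted p = 3.69e-07; adjusted p = 0.342 with an estimated correlation) were lower. MYC and ribosome biogenesis genes were higher (0 of 24 past, 3 higher adjusted over the list alone, median 0.36, camera adjusted p = 1.15e-08; adjusted p = 0.685 with an estimated correlation), and so was proliferation (0 of 25 past, 2 higher adjusted over the list alone, median 0.13, camera adjusted p = 0.000760; adjusted p = 0.451 with an estimated correlation). Neutrophil maturation was not called (median 0.035, mean -0.075, test direction lower, camera adjusted p = 0.932), and its codes went opposite ways, at -0.57 in A1 and 0.63 in A5.

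Across the 5 comparisons 43 of 150 list tests passed with the preset correlation, from 19 of the 30 lists, and 0 with an estimated correlation. The estimate was 0.713 for the MYC and ribosome biogenesis list, 0.043 for the interferon response and -0.03 for MLL-AF9 targets. The last lies below the preset 0.01, so the loss of calls cannot be put down to correlation between genes alone. The test with an estimated correlation also has only 4 degrees of freedom and so little power. A call lost there is not thereby shown to come from correlation between genes. In the 43 the median, the mean and the test had the same sign. The other 11 lists were not called in any: the HoxB cluster, stem and progenitor, eosinophil, erythroid, T and NK cell, B cell, p53 targets, cell cycle inhibitors, sirtuins and histone H3K9 enzymes, sex-linked and housekeeping genes. Their smallest camera adjusted p was 0.0644, for p53 targets in the difference of effects. Single members of these passed, among them Cdkn2c of the cell cycle inhibitors in both arms. With EPZ4777 in shLUC cells Hoxb4 rose (0.91 ± 0.12), the endothelial protein C receptor Procr rose (1.10 ± 0.15), the Polycomb gene Bmi1 fell (-0.86 ± 0.14), and B2m, of MHC class I, rose (0.84 ± 0.16). Ep300, a histone acetyltransferase, rose (0.79 ± 0.16), and the p53 target Btg2 rose in shLUC cells (0.72 ± 0.14) and in cells labelled shSirt1 (1.08 ± 0.14).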

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

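Tests of the normalization, of days in drug, of the size of the effect, of the adjustment step, of the Sirt1 probe set, of a label swap and of A5 against both shLUC codes were chosen only after the result was seen.

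The monocyte and macrophage list differed between the arms in its EPZ4777 effect by a median of -0.67, by the test of the difference itself (camera adjusted p = 1.50e-05; adjusted p = 0.574 with an estimated correlation). A shift between arrays left by the normalization stays open: 14532 other genes of the same mean level had a median difference of 0.024, but they are most of the array, whose median the normalization itself holds near 0. Signal near the floor of the arrays stays open too: the 17 members above the median level of all genes had a median of -0.20, with quartiles of -1.03 and 0.24. Days in drug stay open as well, since 0 hairpins were measured at both times, so time and hairpin cannot be told apart. A difference by hairpin label stays untested.

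EPZ4777 changed 724 genes in shLUC cells and 72 in cells labelled shSirt1, about 10 times fewer. The A1 array in DMSO stays open as the cause: without it limma called 0 genes in cells labelled shSirt1 against 353 in shLUC cells (2187 and 3864 at an unadjusted p under 0.05), but that leaves 1 array in its group, and 0 were also called there without either shLUC array in DMSO (2248 unadjusted). The covariance over genes of the 2 codes' effects in cells labelled shSirt1 was 0.953 times that in shLUC cells. Bootstraps of genes, which are not independent, gave percentile limits of 0.889 and 1.02. The SD over genes of the effects was 0.43 in cells labelled shSirt1 and 0.42 in shLUC cells. An effect far smaller over all genes was thus not seen, while a slightly smaller one stays open. The step of the Benjamini-Hochberg adjustment stays open as an explanation. At an unadjusted p under 0.05 the counts (3945 and 2876) differed by 1.37 times. Chance gives 910 in each arm, which draws that ratio toward 1 whatever the cause, so it does not single out the step. The gap also moved with the fit, at 1316 against 404 genes with the code as a fixed block. A biological difference by hairpin or time stays untested.

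Sirt1 was lower on the A1 arrays and not on the A5 arrays. The lowest shLUC level was 9.44, above the midpoint of 9.17 between A1 and shLUC. That argues against a swap of A5 with shLUC arrays only if the true A5 cells had Sirt1 as low as A1. A swap with a weaker hairpin stays open. Cells in A5 with the same expression as shLUC cells are argued against in DMSO. There 64 genes lay 1 log2 or more outside both A4 and D11, against 4 for A4 and 18 for D11 in the same role. The same way in DMSO and in EPZ4777 lay 37, against 1 for A4 and 6 for D11. In EPZ4777, though, A5 was at 21 days and both A4 and D11 at 6. No time is given for the DMSO arrays, so time in culture stays open as the reason. In DMSO the cholesterol synthesis list on A5 lay at -0.59 and -0.75 from A4 and D11 (18 of 18 genes lower), with A4 at -0.12 from D11, and in EPZ4777 at -0.39 and -0.46 against -0.16, while an earlier test, on the median A5 minus D11 difference of 453 genes apart in A1 and A4, did not decide (0.16, and 0.11 and 0.52 in other pairings). A probe set that misses the targeted RNA stays open: A1 lay at -2.89 SD from the shLUC mean in the treatment with the smaller distance, but this restates the pattern with an SD of 2 arrays. A single wrong label of A5, a weaker hairpin in A5 or a culture apart from the shLUC cells for another reason was not tested.

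By the same test of the difference, the effects on the neutrophil maturation list differed by a median of 0.75 and on MYC and ribosome biogenesis genes by 0.39, calls that ended with an estimated correlation (adjusted p = 0.887 and 0.611). Between the labels the neutrophil list's median was -0.89 in DMSO and 0.035 in EPZ4777. The median differences of effects were -0.40 for FOXO targets, -0.35 for stroma, -0.29 for the interferon response, -0.28 for antigen presentation and dendritic genes and -0.17 for the DOT1L and MLL complex, each with adjusted p = 0.574 with an estimated correlation. In the fit with the code as a block, the effects differed by -3.47 for C1qb, -3.63 for Mmp13 and 3.59 for Smad1. Among 10092 probe sets without a single gene symbol, outside the gene results, 163 passed with EPZ4777 in shLUC cells, 4 in cells labelled shSirt1 and 19 between the hairpins in EPZ4777.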

How the results depend on the processing

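Fits without both A1 or both A5 arrays were chosen after seeing the data, and the other alternatives before. Below, the 5 gene counts are for EPZ4777 in shLUC cells (724), in cells labelled shSirt1 (72), the difference (0 by limma, 1221 at an unadjusted p under 0.05), and the hairpins in DMSO (0, 985 unadjusted) and in EPZ4777 (56). Gene counts not given stayed within 1.5 times. The cause of a move was not tested, except that fewer arrays or genes enter some fits. An array left out also takes its pair out of the shared spread. In shLUC cells the count was 1470 with every probe set by itself, 1424 for genes above the median level, 1316 with the code as a fixed replicate block, 2379 as a random one, 4 at adjusted p under 0.01, 1958 under 0.1, 234 at 1 log2 or more and 402 with only the 4 arrays. In cells labelled shSirt1 it was 404 with the fixed block, 504 with the random one, 0 under 0.01 (limma; 2876 unadjusted), 263 under 0.1 and 0 with only the 4 arrays (2470 unadjusted). The difference had 3 with either block. The hairpins in EPZ4777 had 120 with every probe set, 2 under 0.01, 245 under 0.1 and 14 with only the 4 arrays. Without both A1 arrays the counts were 402, 14 and 129 for the shLUC, labelled shSirt1 and EPZ4777 hairpin comparisons, and without both A5 arrays 402, 145, 69 (difference) and 203 (DMSO). Leaving out 1 array gave 0 to 1031, 0 to 205, 0 to 89, 0 to 155 and 0 to 73 for the 5 counts, 0.494 to 0.693 for the correlation of effects (0.649) and 0 to 90 for the 44 shared genes. The shared genes numbered 248 with the fixed block, 0 under 0.01 and 173 under 0.1. The effect in the codes labelled shSirt1 over that in the other shLUC code was 0.577 for genes picked in A4 and 1.01 for those picked in D11, and 0.770 and 1.44 at 2 log2 or more. Of the list tests 43 passed, against 0 with an estimated correlation, 2 in fry's directional test and 26 of 135 for genes above the median level (3 of 13 kept in shLUC cells, with 7 in cells labelled shSirt1, 3 for the difference, 8 in DMSO and 5 in EPZ4777), where stroma in cells labelled shSirt1 turned direction (adjusted p = 0.977). The block changed no other list call than those given, and the named genes whose calls it changed with EPZ4777 in an arm included Cdk6, Hoxa7, Meis1, Cd177, Lcn2 and Igf1. With 1 array left in a group, that array was assumed to vary like the others.

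Of 103 calls of named genes 102 were kept with median centring, 94 with quantile normalization, 87 with the mean of a gene's probe sets, 40 with only the 4 arrays and 1 when either shLUC array in DMSO was left out. The fixed block kept 77 of 78. Over all settings 0 named genes turned direction, counted where the gene passed in at least 1 of the 2 fits, against 2179 cases unchanged in call, 856 lost and 9 gained. No detection calls were used, so a gene near the lower quartile (3.75 to 3.84), such as C1qb at 3.85 in cells labelled shSirt1 in DMSO, has no measured fall below it, and its folds are limited by the background.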

Other observations

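The A1 array in DMSO stood apart from the other 7 in genes of the stroma list and in others, all chosen after their values were seen. Col3a1 was at 6.92 there and between 2.84 and 3.13 elsewhere, Dcn at 7.27 against 4.48 to 4.79, and Col1a2 at 6.74 against 5.21 to 5.39. Ifi27l2a, an interferon-inducible gene, was at 9.14 on that array and between 4.98 and 7.50 elsewhere. Ppargc1a, a coactivator of mitochondrial genes, was at 6.20 there and between 3.07 and 3.89 elsewhere. The spread between the 2 arrays of a group was 0.43 (SD, log2) for the DMSO arrays labelled shSirt1, 0.36 and 0.34 for the EPZ4777 arrays labelled shSirt1 and shLUC, and 0.21 for shLUC in DMSO.

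Ltf and Mmp9 had distant levels on the 2 arrays of each EPZ4777 group. Ltf, lactoferrin, was at 11.27 in D11 and 7.26 in A4, and at 12.15 in A5 and 8.10 in A1. Mmp9, gelatinase B, was at 10.21 in D11 and 6.22 in A4, and at 10.05 in A5 and 5.71 in A1. In DMSO the 2 shLUC arrays were at 6.33 and 6.92 for Ltf and at 5.53 and 6.46 for Mmp9. Lcn2 lay closer, at 13.44 in D11 and 12.07 in A4, and at 13.32 in A5 and 12.39 in A1, all in EPZ4777. The difference between codes was not tested. Ltf and Mmp9 were chosen after their values were seen, and neither passed the test with EPZ4777 in either arm.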
